A study of Homo sapiens with 15 samples.

How the data were processed

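The samples were bone marrow flushed from the femurs of SCID-beige mice carrying MM.1S human myeloma cells, with 3 libraries for each of the 5 groups. Per the labels' protocols, RNA was extracted with Trizol from frozen cell pellets and libraries were made with a stranded total RNA kit after ribosomal RNA depletion. Per the submitters' processing notes, reads were aligned with STAR 2.5.4b to GRCh37 and counted per gene with featureCounts 1.6.1. The deposited values are raw read counts for 57773 Ensembl genes in each of the 15 libraries, and 0 lines lack a gene identifier. The strand setting, the annotation release and how mouse reads were handled are not given in the sources used here. Because the pellets held mouse cells as well, reads from conserved mouse transcripts can have aligned to human genes.

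The count per library summed to 4500326 to 13161087, and genes of mitochondrial DNA held 35.0% to 40.3% of it. Symbols came from GENCODE 29 and named 52338 of the identifiers. The 5435 without a name held 1.07% of the counts. Samples were grouped by their titles, and no 2 libraries of a group agreed within sampling noise.

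Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors, R 4.3.3). Genes were kept by filterByExpr with a minimum count of 10, which left 13085. All 15 libraries entered 1 model with a common biological coefficient of variation of 0.171, and Benjamini-Hochberg adjusted p under 0.05 counted as passing. The 9 comparisons were each treatment against PBS, the combination and the delayed combination against bortezomib, the combination against elesclomol, the delayed combination against the combination, and the interaction. CPM use TMM-scaled library sizes. The 39 gene lists, drawn up before the data were examined as were the comparisons, the tests and the rule for named genes, held 772 genes, of which 761 were found in the counts. The 35 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. The metallothionein, T and NK cell, megakaryocyte and endothelial lists had too few tested genes. Principal components and levels per list were computed in R. Exact permutation tests used Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

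The named genes followed a fixed rule. For each treatment against PBS these were up to 8 genes with the highest and 8 with the lowest log2 change among those past the threshold with a mean of at least 3 log2 CPM in the higher group and no overlap between the 3 and 3 libraries, and up to 4 and 4 for other comparisons. If fewer passed, all were named. Clone names, pseudogenes, antisense and uncharacterised genes, ribosomal and small RNAs, immunoglobulin and T cell receptor segments and cluster histones were left out of this part. Up to 4 members with the smallest p were taken from each list called, 10 genes were given in every comparison whether or not they changed, and where fewer than 5 genes passed the 5 smallest p were given as not passing. Further genes could be named as examples of a fixed list with a count.

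Alternatives fixed beforehand were DESeq2 1.42.0 and its size factors, limma voom with quality weights, no filter, a mean of at least 3 log2 CPM, only the groups compared, the replicate number as a block, the host marker level as a covariate, library sizes without the most abundant RNAs, a change of at least 2-fold, and leaving out each library in turn. The host marker level was the mean log2 CPM over the erythroid, granulocyte, macrophage, endothelial and stromal markers. For these lists the covariate holds the genes under test, so a lost or reversed call is partly built in. A correction for GC content and gene length (loess, span 0.3, for 12794 genes or 97.8% of those tested) and leaving out the 3 GC-rich libraries were added after seeing the data. So was a fit of the bortezomib and combination libraries alone with the replicate number as a block. Their same-numbered libraries deviated together from the group means (correlations 0.655, 0.523 and 0.118, or 0.520, 0.377 and 0.100 after the correction), a pairing taken from the data, for which the labels give no source. Bortezomib 2 with combination 3 reached 0.222 (0.144 after it), above the third pair. The other unmatched pairs lay at -0.588 to 0.0557.

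The code was tested on simulated counts for the 13085 genes with 50 genes changed at each fold. For bortezomib against PBS it recovered 26% of 1.5-fold, 80% of 2-fold, 96% of 3-fold and 94% of 4-fold changes, for elesclomol 36%, 78%, 90% and 98%, for the combination 24%, 74%, 94% and 94%, and for the delayed combination 26%, 84%, 96% and 94%. False calls were 3.27%, 5.03%, 2.05% and 3.85% of all calls. A simulated GC trend gave 2797 false calls before the correction and 0 after it. A list shifted by 1.5-fold was found (adjusted p = 9.46e-42) with 0 other lists called. Splits of the real libraries called up to 21 lists, so that 0 does not carry over to them.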

Results

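Gene expression was measured by total RNA sequencing in 15 bone marrow samples from mice carrying MM.1S tumours. MM.1S is an established human multiple myeloma cell line, used here with a green fluorescent protein and a luciferase reporter. SCID-beige mice, a strain with severely impaired lymphocytes, received the cells by vein and entered the study once their bioluminescence passed a set level. The 5 groups were PBS, bortezomib at 0.25 mg/kg, elesclomol at 25 mg/kg, both drugs from the start (combination), and bortezomib with elesclomol begun 14 days later (delayed combination). Bortezomib is a proteasome inhibitor used against myeloma, and elesclomol is a copper ionophore that carries copper into cells. Each group held 5 treated mice, of which 3 tumours per group were sequenced, so n = 3 throughout. The endpoint was limb paralysis or severe toxicity of the treatment, and the protocol states that marrow was flushed from the femurs at paralysis. Which endpoint each mouse reached, and after how long on treatment, is not stated.

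The deposited gene counts summed to 4500326 to 6287708 per library with PBS, 5458022 to 8449749 with bortezomib and 6602596 to 7977375 with elesclomol. They summed to 6448673 to 9227140 with the combination and 11060930 to 13161087 with the delayed combination. Levels are CPM, counts scaled to library size, as mean ± SD (n = 3). Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p over 13085 genes. A list is given as the median ± SD of its tested genes' log2 changes and camera's adjusted p over 35 lists. EdgeR's p measures spread between mice, while camera sets a list against other genes at a preset correlation. The 4 comparisons with PBS share its 3 libraries.

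The libraries differed most along an axis that followed the GC content of the genes. The first principal component held 32.9% of the variance, and it set bortezomib 1, combination 1 and delayed combination 2 apart from the rest. The correlation across genes between a library's deviation from the mean and GC content was 0.51 in bortezomib 1, 0.49 in combination 1 and 0.32 in delayed combination 2, against -0.29 to -0.35 in the PBS libraries. Genes are not independent replicates, so these correlations carry no p. MALAT1, a long noncoding RNA kept in the nucleus, stood at 1385, 1581 and 1993 CPM in those 3 libraries and at 3896 to 4549 CPM with PBS. Pearson correlations between replicates were 0.984 to 0.986 with PBS and 0.956 to 0.982 with the combination.

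**Figure D1:**
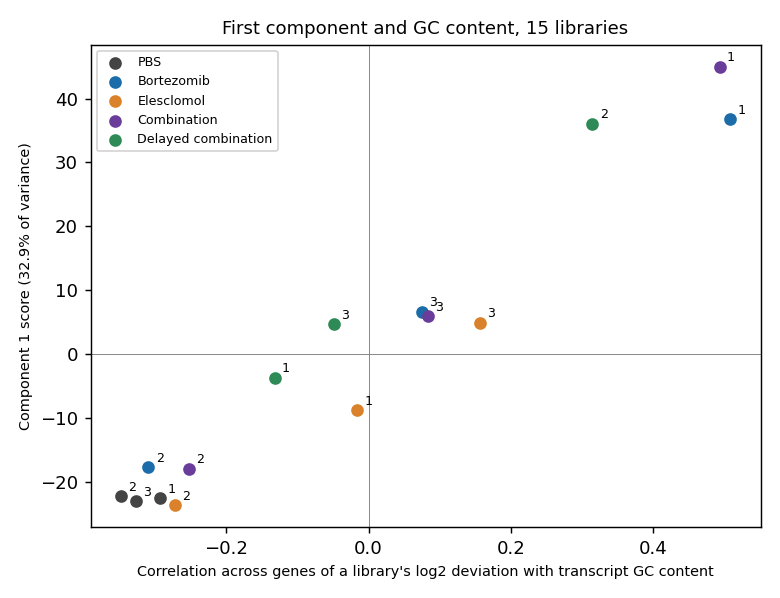
Score on the first principal component (32.9% of the variance, y axis) against the correlation of each library's deviations with transcript GC content (x axis), 1 point per library, coloured by group and marked with its replicate number. Bortezomib 1 (0.51), combination 1 (0.49) and delayed combination 2 (0.32) lie at the upper right, and the PBS libraries (-0.29 to -0.35) at the lower left.

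The comparison of bortezomib alone with PBS is the one named in the series title. The 5 lists below were higher with bortezomib by small amounts, but heat shock genes were not called (median level 5.90 ± 0.32 against 6.12 ± 0.11 log2 CPM). In the unfolded protein response of the endoplasmic reticulum (ER), 19 of 20 genes lay above 0 (median 0.27 ± 0.20). SYVN1, a ubiquitin ligase of the ER membrane, stood at 111 ± 6.48 against 81.5 ± 2.39 CPM (0.45 ± 0.12). HERPUD1, which acts in ER-associated degradation, was at 479 ± 123 against 315 ± 55.6 CPM (0.61 ± 0.21). In the integrated stress response, driven by ATF4, 16 of 20 genes lay above 0 (median 0.33 ± 0.36). The subunits of an amino acid transporter led it, SLC7A5 (0.82 ± 0.20) and SLC3A2 (0.44 ± 0.14). In the 19S cap of the proteasome 16 of 18 lay above 0 (median 0.24 ± 0.17), with the ubiquitin receptor ADRM1 at 0.41 ± 0.12. In the 20S core 9 of 13 lay above 0 (median 0.25 ± 0.19), with PSMB2 at 0.47 ± 0.16. Among autophagy and lysosome genes 18 of 21 lay above 0 (median 0.18 ± 0.19), with the cargo receptor SQSTM1 at 196 ± 31.3 against 132 ± 5.7 CPM (0.57 ± 0.15). Camera's adjusted p for these 5 lists ran from 6.63e-06 to 0.0134, and none held with an estimated correlation (0.569 to 0.624). Adjusted over the list alone, 1 gene each rose in the ER, ATF4 and autophagy lists and 0 in both proteasome lists. The 20S list missed the threshold without bortezomib 1 (adjusted p = 0.122) or PBS 1 (0.0517).

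Genes of growth and energy metabolism were higher with bortezomib too. Of 47 cytoplasmic ribosomal protein genes 44 lay above 0 (median 0.19 ± 0.16), with RPL8 at 689 ± 94.1 against 531 ± 25.4 CPM, and the median was 0.12 without the 3 GC-rich libraries (adjusted p = 1.57e-04). Of 43 mitochondrial ribosomal protein genes 34 lay above 0 (median 0.16 ± 0.20), with MRPL4 at 0.34 ± 0.12. Among targets of the growth regulator MYC 19 of 22 genes lay above 0 (median 0.22 ± 0.16), led by the spermidine synthase SRM (0.56 ± 0.15). The respiratory chain had a median of 0.16 ± 0.17 over 38 genes of complex I, such as NDUFC1 (0.24 ± 0.08). Its median was 0.18 ± 0.10 over 34 genes of complexes III, IV and V, such as ATP5MF (0.34 ± 0.14). Glycolysis (0.30 ± 0.14, 16 genes) included the pyruvate kinase PKM at 0.50 ± 0.19. The citric acid cycle and genes of the antioxidant regulator NRF2 had medians of 0.20 ± 0.14 and 0.21 ± 0.22 over 16 genes each. Genes of DNA synthesis had a median of 0.16 ± 0.16 over 23, with MCM2 at 0.31 ± 0.13. Over these 9 lists camera's adjusted p ran from 4.06e-06 to 0.014, and from 0.569 to 0.654 with an estimated correlation, so that none held. In the MYC list 1 gene rose when adjusted over the list alone, and 0 genes passed in the other 8 lists. The GC-rich library bortezomib 1 moved with these lists. Without it complex I (adjusted p = 0.430), complexes III to V (0.116), the mitochondrial ribosome (0.117), S phase (0.540) and NRF2 (0.0527) missed the threshold. So did S phase without PBS 1 (adjusted p = 0.207) and NRF2 without bortezomib 3 (0.0542).

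Among genes of cell death, BCL2L11, which encodes the pro-apoptotic BH3-only protein BIM, was at 338 ± 151 against 153 ± 29.4 CPM with bortezomib (1.14 ± 0.30). The related BMF was at 15.3 ± 2.26 against 9.58 ± 2.09 CPM (0.68 ± 0.23). Adjusted over the list alone, 3 of the 7 BH3-only genes rose, with a median of 0.32 ± 0.46 (adjusted p = 0.0114 by camera, and adjusted p = 0.569 with an estimated correlation). Lower with bortezomib were the immediate early genes, which growth factors and stress switch on within minutes. Of 16, 14 lay below 0 (median -0.40 ± 0.47), with IER2 at 11.8 ± 3.0 against 21 ± 3.34 CPM and the transcription factor JUN at 243 ± 9.64 against 478 ± 77.1 CPM (adjusted p = 0.00115 by camera, and adjusted p = 0.569 with an estimated correlation). Among genes of the G2 and M phases 20 of 24 genes lay below 0 (median -0.09 ± 0.43), with the mitotic kinase CDK1 at 66.8 ± 6.02 against 92.3 ± 3.23 CPM (-0.47 ± 0.14) and the centromere protein CENPF at -1.29 ± 0.63 (adjusted p = 0.00221 by camera, and adjusted p = 0.569 with an estimated correlation). The stromal and bone marker list, taken to mark marrow cells, was higher (median 0.94 ± 1.10, 11 genes). Collagens and FN1 were higher, and SPARC, RUNX2 (35.2 against 44.3 CPM), LEPR and PDGFRB lower. COL1A1, a collagen of bone matrix, stood at 22.2 ± 13.8 against 3.32 ± 1.03 CPM (camera adjusted p = 0.0338, or 0.569 with an estimated correlation). Adjusted over the list alone, 0 genes of the immediate early, G2 and M, and stromal lists passed. The stromal list missed the threshold without bortezomib 1 (adjusted p = 0.0837), bortezomib 2 (0.0698) or PBS 2 (0.264). The G2 and M list missed it without bortezomib 2 (adjusted p = 0.480). With the host marker level as a covariate, the stromal list (0.0607) missed it. After the GC and length correction, the S phase (0.0685) and complex I (0.212) lists missed it. Without the 3 GC-rich libraries, the complex III to V (0.0642), mitochondrial ribosome (0.0681), 20S (0.0681), stromal (0.152), complex I (0.334) and S phase (0.451) lists missed it.

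No single gene passed the test with bortezomib alone. The smallest p belonged to PDZRN4, at 3.87 ± 0.163 against 10.3 ± 1.08 CPM (-1.41 ± 0.23, edgeR adjusted p = 0.193). It was followed by BASP1 (0.70 ± 0.14), DHX37 (0.57 ± 0.12), HDAC9 (-0.78 ± 0.16) and SPERT (-1.29 ± 0.27), each with an adjusted p of 0.419. The bortezomib and PBS libraries did not overlap for any of the 5. EdgeR called 0 genes, with 1388 at an unadjusted p under 0.05, whereas DESeq2 called 2 and limma voom 741. Among all tested genes 20.2% had bortezomib and PBS libraries that did not overlap, against 10% by chance. Without bortezomib 1 the count was 3. Of the 35 lists tested, 18 were called, 16 higher and 2 lower.

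Elesclomol alone was the treatment with single genes past the threshold, 5 higher and 4 lower than PBS by edgeR. DUSP2 (ENSG00000158050), a nuclear phosphatase that switches off MAP kinases, fell furthest (-1.97 ± 0.25, 5.6 ± 0.561 against 21.9 ± 2.58 CPM, adjusted p = 0.00574). PHLDA1 (ENSG00000139289), a gene induced by growth factor signalling, fell as well (-1.29 ± 0.17, 39.7 ± 4.8 against 96.8 ± 9.05 CPM, adjusted p = 0.00574). So did the class IIa histone deacetylase HDAC9 (ENSG00000048052; -1.19 ± 0.16, 43.6 ± 3.11 against 99.5 ± 14.6 CPM, adjusted p = 0.00804). FRMD6 (ENSG00000139926), a FERM domain protein of the Hippo pathway, was the last of the 4 (-1.07 ± 0.17, 15.1 ± 0.15 against 31.7 ± 1.13 CPM, adjusted p = 0.0173). FBXO32 (ENSG00000156804), the ubiquitin ligase subunit atrogin-1 and a target of FOXO factors, rose most (1.65 ± 0.24, 28.7 ± 5.91 against 9.31 ± 3.48 CPM, adjusted p = 0.0109). The thrombin receptor F2R (ENSG00000181104) rose next (0.99 ± 0.15, 17.3 ± 1.98 against 8.67 ± 0.32 CPM, adjusted p = 0.0109). DAPK1 (ENSG00000196730), a calmodulin-regulated kinase linked to apoptosis, rose too (0.87 ± 0.12, 133 ± 3.99 against 72.7 ± 3.6 CPM, adjusted p = 0.00804). BASP1 (ENSG00000176788), a membrane-bound signalling protein, was also higher (0.84 ± 0.14, 78.2 ± 5.18 against 43.8 ± 2.06 CPM, adjusted p = 0.025). NXPE3 (ENSG00000144815) completed the 9 (0.78 ± 0.09, 695 ± 37.3 against 406 ± 20.8 CPM, adjusted p = 0.00574).

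**Figure D2:**
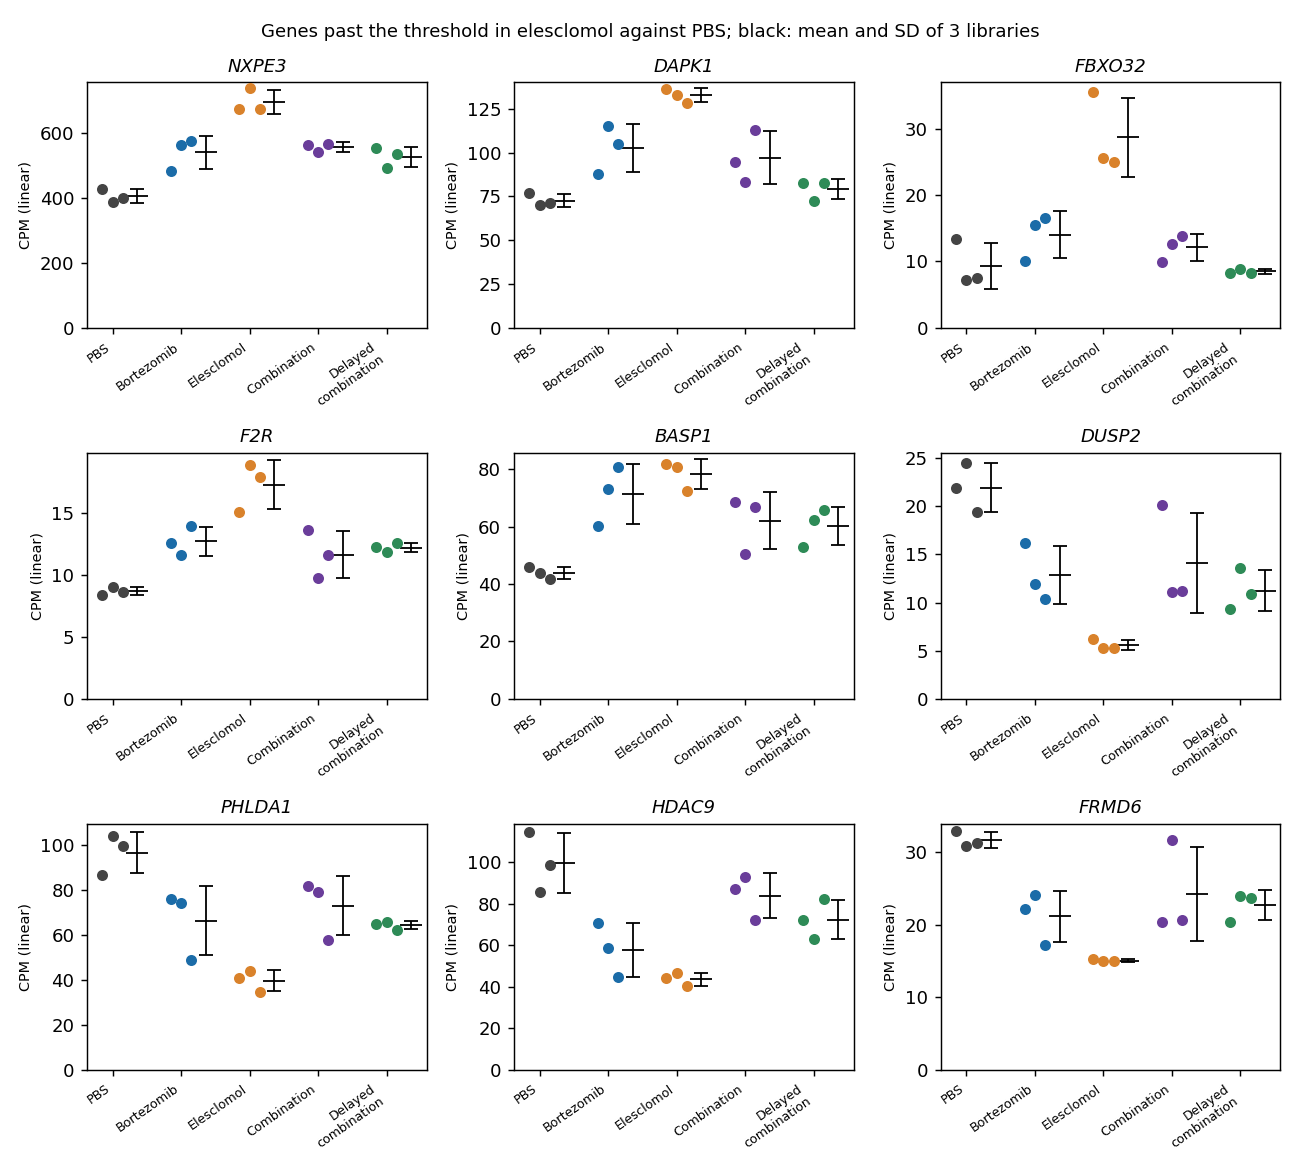
CPM of the 9 genes that passed the test in elesclomol against PBS, 1 panel per gene, with each library as a point and mean ± SD (n = 3) for the 5 groups. DUSP2 stood at 5.6 ± 0.561 against 21.9 ± 2.58 CPM in elesclomol and PBS, and FBXO32 at 28.7 ± 5.91 against 9.31 ± 3.48 CPM.

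All 9 genes had elesclomol libraries that did not overlap PBS, as 19.8% of tested genes did against 10% by chance. The count fell without any 1 library, to 5, 4 and 1 without PBS 1, 2 and 3. It was 4, 6 and 1 without elesclomol 1, 2 and 3, and all 9 genes kept their direction. DESeq2 called 47 genes and limma voom 54, and 4 genes passed with the host marker level as a covariate. After the GC and length correction 7 of the 9 still passed. HDAC9 did not (-1.08 ± 0.28, adjusted p = 0.268), since its SE widened while its log2 change moved little, and neither did BASP1 (0.78 ± 0.14, adjusted p = 0.0564).

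Immediate early genes were the list furthest below PBS with elesclomol. Of 16 genes 15 lay below 0 with a median of -1.25 ± 1.05, and 10 fell when adjusted over the list alone. IER2 stood at 7.75 ± 1.26 against 21 ± 3.34 CPM (-1.45 ± 0.26), and JUN at 127 ± 54.8 against 478 ± 77.1 CPM (-1.92 ± 0.43). The zinc finger factors EGR3 and EGR2 were at -3.08 ± 0.64 and -2.97 ± 0.66 (adjusted p = 2.11e-21 by camera, and adjusted p = 0.0557 with an estimated correlation). Among heat shock genes 16 of 24 genes lay below 0 (median -0.19 ± 0.76), and 7 fell when adjusted over the list alone. The constitutive chaperone HSPA8 was at 636 ± 90.0 against 933 ± 32.6 CPM (-0.55 ± 0.13). The inducible HSPA1B was at 22.7 ± 11.2 against 144 ± 36.4 CPM (-2.66 ± 0.61), uncertain because it shares reads with its near-identical copy HSPA1A (adjusted p = 9.68e-07 by camera, and adjusted p = 0.261 with an estimated correlation). Among hypoxia genes 9 of 14 genes lay below 0 (median -0.22 ± 0.40), and 4 fell when adjusted over the list alone. Among them were the peptide hormone ADM at 135 ± 11 against 287 ± 20.2 CPM and the growth factor VEGFA at 15.8 ± 0.919 against 23.3 ± 3.88 CPM (adjusted p = 5.85e-04 by camera, and adjusted p = 0.261 with an estimated correlation). Cholesterol synthesis was lower too, where 15 of 21 genes lay below 0 (median -0.20 ± 0.32) (adjusted p = 3.14e-04 by camera, and adjusted p = 0.837 with an estimated correlation).

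Cell cycle genes went both ways with elesclomol. Among genes of the G2 and M phases 23 of 24 genes lay below 0 (median -0.21 ± 0.29), with CDK1 at -0.38 ± 0.14 and the kinase AURKA at -0.41 ± 0.25 (adjusted p = 1.76e-04 by camera, and adjusted p = 0.606 with an estimated correlation). Among genes of DNA synthesis, in contrast, 18 of 23 genes lay above 0 (median 0.13 ± 0.15), with MCM6 at 0.27 ± 0.12 (adjusted p = 0.0189 by camera, and adjusted p = 0.851 with an estimated correlation). The ER list was higher, and 17 of 20 genes lay above 0 (median 0.11 ± 0.19), including XBP1, the factor that drives plasma cell secretion, at 2867 ± 192 against 2227 ± 228 CPM (adjusted p = 0.00575 by camera, and adjusted p = 0.837 with an estimated correlation). Markers of marrow cells were higher as well. In the stromal and bone list 9 of 11 genes lay above 0 (median 1.53 ± 1.00) and 3 rose when adjusted over the list alone. Fibronectin, FN1, was at 30.2 ± 10.6 against 17.6 ± 3.36 CPM and COL1A1 at 18.5 ± 12 against 3.32 ± 1.03 CPM (adjusted p = 1.90e-05 by camera, and adjusted p = 0.234 with an estimated correlation). All 7 granulocyte markers lay above 0 (median 1.45 ± 0.53), among them the collagenase MMP8 at 4.97 ± 4.47 against 1.0 ± 0.0876 CPM, with 10.1 CPM in elesclomol 1 (adjusted p = 0.00762 by camera, and adjusted p = 0.606 with an estimated correlation). Another was NCF1, which has near-identical pseudogenes and is uncertain. Adjusted over the list alone, 0 genes of the cholesterol, ER, G2 and M, S phase and granulocyte lists passed. Without PBS 3, the ER (adjusted p = 0.0532) and granulocyte (0.0568) lists missed the threshold. Without elesclomol 3, the S phase (adjusted p = 0.0575) and ER (0.115) lists missed the threshold. Only 1 list missed it without each of PBS 1 (S phase, adjusted p = 0.291), elesclomol 1 (granulocyte, 0.558) and elesclomol 2 (S phase, 0.106). With the host marker level as a covariate the stromal median was 0.54 (adjusted p = 0.0105), the granulocyte list changed sign (adjusted p = 0.423), and the cholesterol (0.0911), ER (0.182) and G2 and M lists (0.386) missed the threshold.

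With both drugs from the start, the immediate early genes were again far below PBS. All 16 lay below 0 (median -1.15 ± 0.92) and 9 fell when adjusted over the list alone. JUN was at 115 ± 74.8 against 478 ± 77.1 CPM (-2.05 ± 0.43), the phosphatase DUSP1 at 36.3 ± 20.9 against 182 ± 41 CPM (-2.32 ± 0.53), FOSB at -3.02 ± 0.71 and IER2 at -1.17 ± 0.26 (adjusted p = 6.69e-13 by camera, and adjusted p = 0.167 with an estimated correlation). The ER list was higher: 18 of 20 genes lay above 0 (median 0.30 ± 0.21) and 10 rose when adjusted over the list alone. Among them were SYVN1 at 121 ± 17.2 against 81.5 ± 2.39 CPM (0.58 ± 0.12) and the protein disulfide isomerases PDIA3 (0.48 ± 0.13) and PDIA4 (0.40 ± 0.12) (adjusted p = 2.31e-06 by camera, and adjusted p = 0.737 with an estimated correlation). Among heat shock genes 19 of 24 genes lay below 0 (median -0.21 ± 0.44), and 7 fell when adjusted over the list alone. The cytosolic chaperone HSP90AA1 was at 71 ± 7.68 against 117 ± 16.2 CPM (-0.72 ± 0.15) and the mitochondrial HSPD1 at 313 ± 9.4 against 414 ± 19.5 CPM (adjusted p = 6.63e-05 by camera, and adjusted p = 0.737 with an estimated correlation). Of the 13 protein genes of mitochondrial DNA 12 lay below 0 (median -0.48 ± 0.27), such as MT-ND4 of complex I at 1072 ± 228 against 1842 ± 150.0 CPM and the oxidase subunit MT-CO1 at 2457 ± 411 against 3416 ± 163 CPM (adjusted p = 4.22e-05 by camera, and adjusted p = 0.776 with an estimated correlation). The nuclear genes of complexes III to V were higher (0.15 ± 0.12, COX4I1 0.30 ± 0.12; adjusted p = 0.0125 by camera, and adjusted p = 0.776 with an estimated correlation). So were ribosomal proteins (0.22 ± 0.15; adjusted p = 1.50e-05 by camera, and adjusted p = 0.776 with an estimated correlation).

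Interferon-induced genes were lower with the combination, and 17 of 22 genes lay below 0 (median -0.29 ± 0.50). IFIT1, an antiviral RNA-binding protein, was at 2.29 ± 1.3 against 5.9 ± 1.08 CPM and IFIT3 at 3.73 ± 0.684 against 6.15 ± 1.78 CPM, while ISG20 lay above PBS (0.45 ± 0.17). Genes of the G2 and M phases were lower (-0.13 ± 0.39), with CDK1 at 64.6 ± 14.6 against 92.3 ± 3.23 CPM and the proliferation marker MKI67 at 369 ± 61 against 497 ± 96.2 CPM. All 14 histone genes lay below 0 (-0.22 ± 0.12), such as the linker histone HIST1H1E (-0.23 ± 0.15). Autophagy genes were higher (0.19 ± 0.20), including the initiating kinase ULK1 (0.53 ± 0.21) but not UVRAG (-0.39 ± 0.17). These 4 lists had camera adjusted p of 0.00567 to 0.0217, and adjusted p = 0.776 for each with an estimated correlation. Adjusted over the list alone, 0 genes passed in the interferon, G2 and M, histone, autophagy, mitochondrial, complex III to V and ribosomal protein lists. Without PBS 3, the G2 and M (adjusted p = 0.0502) and histone (0.108) lists missed the threshold. Without combination 1, the autophagy (0.129) and complex III to V (0.855) lists missed it. Without combination 3, the G2 and M (0.0934) and histone (0.178) lists missed it. Without combination 2, the histone list (0.289) missed it. After the GC and length correction, the autophagy list (0.109) missed it. Without the 3 GC-rich libraries, the autophagy (0.108) and complex III to V (0.69) lists missed it. The medians were 0.09 for complexes III to V after the correction (adjusted p = 0.0199) and 0.12 for ribosomal proteins without those libraries (0.0242). The stromal list had a median of 1.20 ± 1.22 beside these and did not pass (adjusted p = 0.161).

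Single genes did not pass in the combination. The 5 smallest p belonged to UBALD1 at 13.5 ± 0.292 against 7.51 ± 0.521 CPM (0.85 ± 0.13, edgeR adjusted p = 0.114) and 4 others. These were the endothelial nitric oxide synthase NOS3 (0.64 ± 0.11, adjusted p = 0.132), the ETS factor ETV5 at 52.2 ± 14 against 22 ± 3.53 CPM (1.26 ± 0.21, adjusted p = 0.132), the nuclear IkB protein NFKBIZ at 19.5 ± 4.26 against 44.6 ± 7.78 CPM (-1.19 ± 0.21, adjusted p = 0.147) and the replacement histone H3F3B (-0.65 ± 0.12, adjusted p = 0.158). EdgeR called 0 genes, with 1784 at an unadjusted p under 0.05, DESeq2 called 47 and limma voom 1394. Without combination 2 edgeR called 6. The libraries did not overlap for 22.2% of genes, against 10% by chance, and 4 lists were higher and 6 lower.

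With all libraries in, the delayed combination had the lowest immediate early genes of the 4 treatments. The combination lay lower without the 3 GC-rich libraries (median -1.61 against -1.54). In the delayed combination all 16 lay below 0 (median -1.49 ± 1.06) and 15 fell when adjusted over the list alone. JUN stood at 75.9 ± 19.5 against 478 ± 77.1 CPM (-2.65 ± 0.44), EGR1 at 9.94 ± 3.61 against 77.6 ± 14.8 CPM (-2.96 ± 0.62) and FOSB at 6.93 ± 4.46 against 75.9 ± 17.6 CPM (-3.45 ± 0.71). This call held with an estimated correlation (adjusted p = 4.16e-24 by camera, and adjusted p = 0.0359 with an estimated correlation). The median level over the list was 5.58 ± 0.05 log2 CPM with PBS (SD, n = 3), 4.92 ± 0.18 with bortezomib, 3.56 ± 1.01 with elesclomol, 3.62 ± 1.01 with the combination and 3.17 ± 0.50 with the delayed combination. Stromal and bone markers were the list furthest above PBS: 8 of 11 genes lay above 0 (median 2.51 ± 1.51), and 6 rose and 1 fell when adjusted over the list alone. COL1A1 stood at 30.9 ± 19.7 against 3.32 ± 1.03 CPM (3.24 ± 0.80), COL3A1, a fibrillar collagen of soft tissue, at 24.4 ± 16.2 against 3.8 ± 2.11 CPM and COL1A2 at 31.6 ± 19.8 against 5.29 ± 3.77 CPM (adjusted p = 2.99e-05 by camera, and adjusted p = 0.30 with an estimated correlation). Markers of macrophages were higher too: 9 of 9 genes lay above 0 (median 0.54 ± 0.34), with the lysosomal protease CTSS at 222 ± 48.1 against 169.7 ± 8.8 CPM and the myeloid factor SPI1 at 6.29 ± 2.48 against 3.93 ± 1.43 CPM (adjusted p = 0.0223 by camera, and adjusted p = 0.604 with an estimated correlation).

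**Figure D3:**
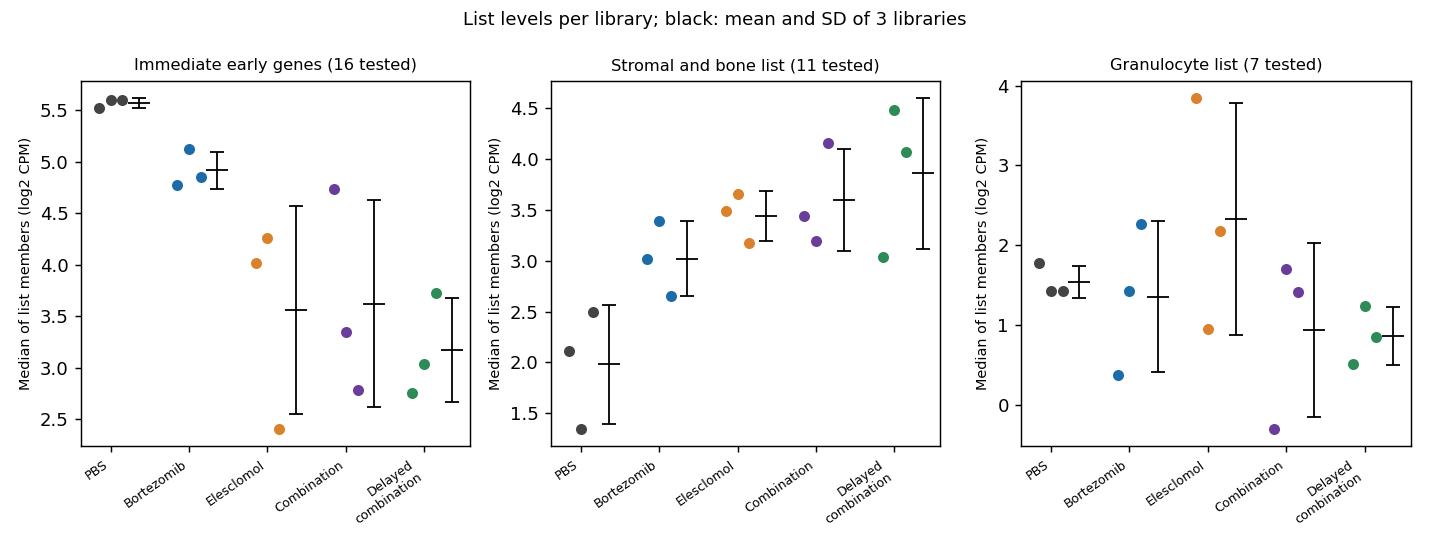
Median log2 CPM per library over the immediate early (16 genes), stromal and bone (11 genes) and granulocyte (7 genes) lists, by group, with mean ± SD (n = 3). Immediate early levels ran from 5.52 to 5.60 with PBS and from 2.75 to 3.73 with the delayed combination, and stromal levels were 1.98 ± 0.58 and 3.86 ± 0.74.

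Growth and metabolic lists were higher with the delayed combination, as they were with bortezomib. Ribosomal proteins had a median of 0.22 ± 0.15 with 43 of 47 genes above 0, such as RPS9 at 124 ± 2.86 against 98.5 ± 5.59 CPM. Mitochondrial ribosomal proteins had 0.16 ± 0.15, such as MRPL24 (0.42 ± 0.12). Complex I stood at 0.19 ± 0.20, with NDUFC1 at 45.4 ± 0.199 against 36.8 ± 0.897 CPM but NDUFV2 at -0.64 ± 0.25, and its median was 0.10 after the GC and length correction (adjusted p = 0.0193). Complexes III to V stood at 0.20 ± 0.10 with 34 of 34 genes above 0, such as ATP5MC1 (0.47 ± 0.14). The citric acid cycle (0.15 ± 0.13) included the fumarase FH (0.39 ± 0.13) and glycolysis (0.19 ± 0.19) PKM (0.38 ± 0.19). The NRF2 list (0.22 ± 0.20) included the glutathione enzyme GCLC (0.29 ± 0.11) and the MYC list (0.14 ± 0.14) the kinase CDK4 (0.31 ± 0.12). The proteasome had medians of 0.13 ± 0.22 in the 19S cap, with ADRM1 at 107 ± 6.28 against 80.8 ± 3.67 CPM, and of 0.19 ± 0.17 in the 20S core, with PSMB4 at 0.40 ± 0.14. The S phase list (0.12 ± 0.15) included CDC6 (0.32 ± 0.15), and the ER list (0.25 ± 0.13) EDEM1 at 556 ± 43 against 442 ± 5.1 CPM and XBP1 (0.33 ± 0.10). Across these 12 lists camera's adjusted p ran from 1.07e-08 to 0.0269, and from 0.576 to 0.604 with an estimated correlation, and 0 genes passed when adjusted over the list alone. Without delayed combination 2, the S phase (adjusted p = 0.0509), glycolysis (0.0922), 19S (0.103), 20S (0.221) and NRF2 (0.221) lists missed the threshold. Without PBS 1, the glycolysis (0.0656), 20S (0.0795), 19S (0.0927) and S phase (0.283) lists missed it. Without delayed combination 1, the glycolysis (0.0525), 20S (0.0538) and S phase (0.315) lists missed it. Without PBS 3, the glycolysis list (0.0626) missed it. With the host marker level as a covariate, the NRF2 list (0.056) missed it. After the GC and length correction, the S phase (0.125) and glycolysis (0.175) lists missed it. Without the 3 GC-rich libraries, the 20S (0.103) and NRF2 (0.147) lists missed it.

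Lower beside the immediate early genes were 3 lists. Among heat shock genes 15 of 24 genes lay below 0 (median -0.17 ± 0.69), and 8 fell and 1 rose when adjusted over the list alone. HSP90AA1 was at 73.8 ± 9.2 against 117 ± 16.2 CPM (-0.67 ± 0.15) and the small heat shock protein HSPB1 at 38.2 ± 2.33 against 65.6 ± 8.5 CPM. Interferon-induced genes had a median of -0.28 ± 0.43, with IFIT3 at 3.23 ± 0.038 against 6.15 ± 1.78 CPM and the signal transducer STAT2 at 81.8 ± 4.47 against 103 ± 5.66 CPM. Histone genes had a median of -0.23 ± 0.20, with HIST1H2BD at 93.3 ± 2.84 against 137 ± 18.4 CPM. For the 3, camera's adjusted p was 8.72e-04 to 0.00274, and 0.576 to 0.604 with an estimated correlation. No gene of the interferon, histone and macrophage lists passed when adjusted over the list alone (0 by edgeR). The 5 genes with the smallest p did not pass: NFKBIZ at 16.1 ± 3.17 against 44.6 ± 7.78 CPM (-1.46 ± 0.21, adjusted p = 0.0533), IER2 (-1.54 ± 0.25), NOS3 (0.60 ± 0.11), TMEM178B (-1.18 ± 0.21) and the small GTPase RHOB at 76.5 ± 24.7 against 243 ± 18.5 CPM (-1.67 ± 0.28), the last 4 with an adjusted p of 0.123. EdgeR called 0 genes, with 1447 at an unadjusted p under 0.05, whereas DESeq2 called 47 and limma voom 168. Without delayed combination 1 the count was 49. The libraries did not overlap for 27.5% of genes, against 10% by chance. Of the lists, 14 were higher and 4 lower. Heat shock genes missed the threshold without delayed combination 1 (adjusted p = 0.0731). The macrophage list missed it without PBS 1 (adjusted p = 0.0818), PBS 3 (0.126) or delayed combination 2 (0.624), with the host marker level as a covariate (0.509) and without the 3 GC-rich libraries (0.588).

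Adding elesclomol to bortezomib, the combination against bortezomib, went with 8 lower lists and no higher one. Immediate early genes lay lowest (14 of 16 genes lay below 0 (median -0.57 ± 0.78)). DUSP1 was at 36.3 ± 20.9 against 152 ± 31.7 CPM (-2.06 ± 0.53) and FOS at 33.6 ± 32 against 143 ± 29.1 CPM (-2.07 ± 0.75), and 1 gene fell when adjusted over the list alone (adjusted p = 1.22e-08 by camera, and adjusted p = 0.555 with an estimated correlation). Among heat shock genes 20 of 24 genes lay below 0 (median -0.15 ± 0.21), with HSP90AA1 at 71 ± 7.68 against 108 ± 23.6 CPM, and 1 fell when adjusted over the list alone. All 13 mitochondrially encoded genes (-0.27 ± 0.15), such as MT-ND2 (-0.47 ± 0.24), and all 14 histone genes (-0.19 ± 0.09), such as HIST1H1B (-0.40 ± 0.18), lay below 0. The S phase list (-0.16 ± 0.12) included the ribonucleotide reductase RRM2 at 244 ± 32.6 against 338 ± 78.6 CPM and the MYC list (-0.14 ± 0.10) nucleolin, NCL (-0.24 ± 0.10). The interferon list (-0.30 ± 0.32) was lower, and the ATF4 list (-0.11 ± 0.23) included the phosphatase subunit PPP1R15A at 27.7 ± 12.8 against 43.6 ± 3.69 CPM. Camera's adjusted p ran from 1.35e-04 to 0.0285 over these 7 lists, and 0.746 for each with an estimated correlation. Without bortezomib 1, the interferon (adjusted p = 0.0615), MYC (0.0951), histone (0.293, direction reversed), S phase (0.524) and ATF4 (0.681) lists missed the threshold. Without combination 2, the heat shock (0.165), MYC (0.435), histone (0.435) and ATF4 (0.933) lists missed it. Only 1 list missed it without each of bortezomib 2 (mitochondrially encoded, adjusted p = 0.251), bortezomib 3 (interferon, 0.209), combination 1 (interferon, 0.17) and combination 3 (histone, 0.26). Leaving out the 3 GC-rich libraries, the interferon (0.132) and histone (0.132) lists missed it.

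Single genes did not pass there. AC010719.1 had the smallest p (1.07 ± 0.17, 27.1 ± 3.44 against 12.8 ± 1.15 CPM, edgeR adjusted p = 0.139), ahead of the lipid flippase ATP8A2 (0.79 ± 0.17), PYROXD2 (1.16 ± 0.26), the linker histone H1FX at 242 ± 33.2 against 383 ± 33.7 CPM and H1FX-AS1 (-0.72 ± 0.17), each with an adjusted p of 0.999. H1FX-AS1 is antisense to H1FX and uncertain, since the strand setting of the counting is not given in the sources used here. By edgeR 0 genes were called, with 554 at an unadjusted p under 0.05, DESeq2 1 and limma voom 35. The libraries did not overlap for 8.19% of genes, against 10% by chance. A fit of these 6 libraries alone with the replicate number as a block, chosen after the values were seen, had 5 genes past the threshold. SOCS3, an inhibitor of cytokine signalling, fell there (-3.03 ± 0.32, edgeR adjusted p = 0.0128), as did H1FX (-0.66 ± 0.09, 0.0487) and the zinc finger factor KLF2 (-0.64 ± 0.08, 0.0482). AC010719.1 rose (1.07 ± 0.12, adjusted p = 0.0146), and the fifth was AC010970.1, a processed pseudogene. The 8 lists kept their calls in that fit, and the erythroid (adjusted p = 0.00763) and B cell lists (0.0432) passed too, the former also without the block in these 6 libraries (0.0106).

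Adding bortezomib to elesclomol, the combination against elesclomol, gave lower interferon-induced genes (20 of 22 genes lay below 0 (median -0.44 ± 0.51)), of which 6 fell when adjusted over the list alone. Among them were IFIT3 at 3.73 ± 0.684 against 7.13 ± 1.79 CPM and MX1 at -0.68 ± 0.22. Hypoxia genes were higher (11 of 14 genes lay above 0 (median 0.25 ± 0.35)), and 2 rose when adjusted over the list alone. The HIF target ANKRD37 was at 148 ± 13 against 87.5 ± 6.79 CPM and VEGFA at 22.6 ± 3.33 against 15.8 ± 0.919 CPM. Cholesterol genes were higher too (18 of 21 genes lay above 0 (median 0.16 ± 0.48)), and 2 rose when adjusted over the list alone. HSD17B7 was at 24.7 ± 2.04 against 14.7 ± 0.599 CPM. Ribosomal proteins (0.14 ± 0.13) and the ER list (0.14 ± 0.20, PDIA3 0.38 ± 0.13, but XBP1 -0.36 ± 0.10) were higher. In contrast, mitochondrially encoded genes (-0.34 ± 0.21, MT-ND5 -0.76 ± 0.28) and S phase genes (-0.12 ± 0.20, RRM2 -0.59 ± 0.17) were lower. Markers of granulocytes (-1.66 ± 1.10, MMP8 -3.40 ± 0.91) and of erythroid cells (-1.98 ± 1.51, HBB 18.7 ± 10.5 against 115 ± 148 CPM, with 286 CPM in elesclomol 1) were lower. Of these lists 1 and 5 genes fell and 0 and 1 rose when adjusted over the list alone. HBB is uncertain because it shares reads with HBD. Over the 9 lists camera's adjusted p ran from 8.06e-06 to 0.0265, and from 0.873 to 0.95 with an estimated correlation. Without elesclomol 1, the ER (adjusted p = 0.0553), erythroid (0.165), cholesterol (0.165) and granulocyte (0.537) lists missed the threshold. Without combination 3, the S phase (0.146), cholesterol (0.146) and ER (0.411) lists missed it. Without combination 2, the erythroid (0.143) and S phase (0.167) lists missed it. Without elesclomol 2, the mitochondrially encoded (0.0938) and ER (0.208) lists missed it. Only 1 list missed it without each of combination 1 (ribosomal protein, adjusted p = 0.531) and elesclomol 3 (S phase, 0.0573). With the host marker level as a covariate, the erythroid (0.225), cholesterol (0.345) and granulocyte (0.98) lists missed it. Leaving out the 3 GC-rich libraries, the granulocyte (0.0564), erythroid (0.0889) and ribosomal protein (0.541) lists missed it.

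The 5 smallest p there, none of them past the threshold, belonged to HDAC9 at 83.8 ± 10.7 against 43.6 ± 3.11 CPM (0.94 ± 0.16), GOLPH3L (0.76 ± 0.13), H1FX-AS1 (-0.96 ± 0.17), the interferon-induced helicase DDX60 (-1.78 ± 0.31) and the RAS pathway inhibitor SPRED1 at 78.1 ± 9.11 against 43.2 ± 1.24 CPM (0.85 ± 0.15), all with an edgeR adjusted p of 0.0888. EdgeR called 0 genes, with 1597 at an unadjusted p under 0.05, DESeq2 50 and limma voom 205. EdgeR called 1 without elesclomol 3. The libraries did not overlap for 16% of genes, against 10% by chance.

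Late elesclomol on top of bortezomib, the delayed combination against bortezomib, again had the immediate early genes lowest (15 of 16 genes lay below 0 (median -1.12 ± 0.86)). Adjusted over the list alone 10 fell, with DUSP1 at 31.4 ± 5.48 against 152 ± 31.7 CPM (-2.28 ± 0.53), FOS at 19 ± 10.5 against 143 ± 29.1 CPM and JUN at 75.9 ± 19.5 against 243 ± 9.64 CPM. This call held with an estimated correlation (adjusted p = 2.41e-24 by camera, and adjusted p = 0.0322 with an estimated correlation). The ATF4 list had 13 of 20 genes below 0 (-0.09 ± 0.36), and 1 gene fell when adjusted over the list alone. PPP1R15A was at 17.4 ± 2.06 against 43.6 ± 3.69 CPM (-1.33 ± 0.27) and the stress factor ATF3 at -0.89 ± 0.35. Heat shock (-0.13 ± 0.29, BAG3 -0.54 ± 0.22), interferon (-0.23 ± 0.29, IFIT3 -0.83 ± 0.25) and histone genes (-0.24 ± 0.10, HIST1H1D -0.38 ± 0.19) were lower. Stromal markers were higher (0.44 ± 0.68, COL3A1 24.4 ± 16.2 against 6.91 ± 2.8 CPM). Over these 5 lists camera's adjusted p ran from 0.00124 to 0.00718, and from 0.669 to 0.999 with an estimated correlation. Of the last 4 lists 0 genes passed when adjusted over the list alone. The smallest p belonged to PPP1R15A, AC010719.1 (0.78 ± 0.17), ANKRD37 (0.69 ± 0.15), TMEM178B (-0.92 ± 0.21) and TIPARP (-0.70 ± 0.16), each with an edgeR adjusted p of 0.813. EdgeR called 0 genes, with 460 at an unadjusted p under 0.05, DESeq2 8 and limma voom 7. It called 4 without bortezomib 1 and 6 without delayed combination 1. The libraries did not overlap for 6.69% of genes, against 10% by chance. Without bortezomib 1, the heat shock (adjusted p = 0.123), ATF4 (0.405) and histone (0.43, direction reversed) lists missed the threshold. Without delayed combination 3, the interferon (adjusted p = 0.246) and ATF4 (0.503) lists missed the threshold. Only 1 list missed it without each of bortezomib 3 (interferon, adjusted p = 0.226), delayed combination 1 (heat shock, 0.401) and delayed combination 2 (stromal, 0.0773). Leaving out the 3 GC-rich libraries, the ATF4 (adjusted p = 0.052), stromal (0.093) and histone (0.626, direction reversed) lists missed the threshold.

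The delayed combination against the combination asks whether the start of elesclomol mattered, and no list median differed by as much as 1. Stromal markers were higher (10 of 11 genes lay above 0 (median 0.71 ± 0.49)), with the matrix protein SPARC at 39.2 ± 4.39 against 26.2 ± 3.92 CPM and the receptor PDGFRB at 0.86 ± 0.39. Immediate early genes were lower (15 of 16 genes lay below 0 (median -0.40 ± 0.36)), with EGR1 at 9.94 ± 3.61 against 20.1 ± 18.1 CPM. All 23 S phase genes (0.11 ± 0.09, CDC45 0.29 ± 0.14) and all 13 mitochondrially encoded genes (0.22 ± 0.06, MT-CO1 0.25 ± 0.19) lay above 0. Complex I (0.08 ± 0.09, NDUFC1 0.16 ± 0.08), complexes III to V (0.07 ± 0.08, UQCRB 0.28 ± 0.13), MYC targets (0.06 ± 0.08, NPM1 0.19 ± 0.10) and the mitochondrial ribosome (0.06 ± 0.09, MRPL16 0.17 ± 0.11) were higher. Camera's adjusted p ran from 7.94e-05 to 0.0407 over the 8 lists, and from 0.609 to 0.872 with an estimated correlation, and 0 genes passed when adjusted over the list alone. The genes with the smallest p were TTLL3 (-0.81 ± 0.18), the phosphodiesterase PDE1B (-0.60 ± 0.14), COL14A1 (-1.11 ± 0.28), DUSP18 (-0.88 ± 0.23) and EIF3J-DT (-0.61 ± 0.16), each with an edgeR adjusted p of 1.00. By edgeR 0 genes were called, with 344 at an unadjusted p under 0.05, and DESeq2 and limma voom 0 each. The libraries did not overlap for 7.59% of genes, against 10% by chance. Without delayed combination 2, the stromal (adjusted p = 0.0518), complex I (0.14), complex III to V (0.229), MYC (0.328) and mitochondrial ribosome (0.528) lists missed the threshold. Without combination 2, the MYC (0.916), complex I (0.916), complex III to V (0.916, direction reversed) and mitochondrial ribosome (0.966, direction reversed) lists missed it. Without combination 3, the mitochondrially encoded (0.0641), MYC (0.0683) and mitochondrial ribosome (0.122) lists missed it. Without combination 1, the immediate early list (0.679, direction reversed) missed it. After the GC and length correction, the complex III to V (0.050) and mitochondrial ribosome (0.19) lists missed it. Leaving out the 3 GC-rich libraries, the immediate early list (0.656, direction reversed) missed it.

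The interaction asks whether elesclomol's log2 change with bortezomib differed from its change without it. HDAC9 was the only gene past the threshold (difference 1.72 ± 0.23, edgeR adjusted p = 0.0229). It stood at 99.5 ± 14.6 CPM with PBS, 57.8 ± 13 with bortezomib, 43.6 ± 3.11 with elesclomol and 83.8 ± 10.7 with both. PDZRN4 (2.06 ± 0.32, adjusted p = 0.0631), DUSP2 (2.11 ± 0.34, 0.0655), PHLDA1 (1.42 ± 0.23, 0.0655) and AL357060.1 (1.44 ± 0.25, 0.0657) came next and did not pass. Its call was lost with the host marker level as a covariate (adjusted p = 0.153) and without elesclomol 3 (0.0789). The count was 0 without PBS 1, PBS 3, bortezomib 2, bortezomib 3, elesclomol 1, elesclomol 2 or combination 2, 2 without combination 1 or combination 3, and 27 without bortezomib 1. DESeq2 called 32 genes and limma voom 310. After the GC and length correction HDAC9 missed the threshold (1.63 ± 0.39, adjusted p = 0.231), since its SE widened while the difference moved little, and the 2 genes past it were others. Among lists, the difference was above 0 for hypoxia (0.28 ± 0.51, 3 genes adjusted over the list alone, ANKRD37 1.03 ± 0.21), immediate early (0.40 ± 1.21, 2 genes, EGR2 3.48 ± 0.85) and G2 and M genes (0.21 ± 0.38, CENPA 0.59 ± 0.31). It was below 0 for S phase (-0.29 ± 0.23, TYMS -0.92 ± 0.34), stromal (-1.04 ± 0.94, COL1A1 -2.70 ± 1.06), granulocyte (-1.33 ± 0.81, MMP8 -3.10 ± 1.45) and MYC genes (-0.25 ± 0.21, SRM -0.64 ± 0.21). So it was for interferon (-0.41 ± 0.47, IFIT3 -0.86 ± 0.36), BH3-only (-0.08 ± 0.95, BCL2L11 -2.29 ± 0.42, 2 genes adjusted over the list alone) and 19S genes (-0.18 ± 0.17, PSMC5 -0.57 ± 0.25). Camera's adjusted p ran from 2.65e-04 to 0.032 over the 10 lists, and from 0.462 to 0.815 with an estimated correlation. Without PBS 3, the BH3-only (adjusted p = 0.053), granulocyte (0.0951) and G2 and M (0.0951) lists missed the threshold. Without combination 1, the interferon (0.0542), granulocyte (0.122) and immediate early (0.605) lists missed it. Without combination 2, the G2 and M (0.090), BH3-only (0.096) and 19S (0.339) lists missed it. Without bortezomib 2, the granulocyte (0.0702) and G2 and M (0.287) lists missed it. Without bortezomib 3, the interferon (0.0582) and granulocyte (0.146) lists missed it. Without elesclomol 1, the G2 and M (0.109) and granulocyte (0.39) lists missed it. Without elesclomol 2, the 19S (0.0556) and BH3-only (0.0603) lists missed it. Without elesclomol 3, the 19S (0.060) and immediate early (0.0716) lists missed it. Only 1 list missed it without each of PBS 1 (19S, adjusted p = 0.0742), PBS 2 (19S, 0.0552), bortezomib 1 (19S, 0.20) and combination 3 (19S, 0.0695). With the host marker level as a covariate, the immediate early (0.0913), stromal (0.0913), granulocyte (0.539, direction reversed) and G2 and M (0.713) lists missed it. Without the 3 GC-rich libraries, the interferon (0.0516), granulocyte (0.0516) and immediate early (0.395) lists missed it.

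Across all 13085 genes, the log2 changes with elesclomol given alone and given on top of bortezomib had a Pearson r of -0.254 (Spearman rho -0.196), from comparisons with no library in common. Of the 9 genes called in either, 1 had the same sign in the other. The log2 changes with bortezomib alone and on top of elesclomol had an r of 0.0698 (rho 0.214), and r was -0.0234 without bortezomib 1, -0.0510 without elesclomol 2 and -0.131 without combination 1. Without bortezomib 3 the first r was -0.0966. Both are correlations across genes, which are not independent replicates.

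Marrow cells of the mouse could contribute reads that align to human genes, so markers of erythroid cells, granulocytes, macrophages, endothelium and stroma were followed. The median level of the 11 stromal markers was 1.98 ± 0.58 log2 CPM with PBS (SD, n = 3), 3.02 ± 0.37 with bortezomib, 3.44 ± 0.24 with elesclomol, 3.59 ± 0.50 with the combination and 3.86 ± 0.74 with the delayed combination. By the mean over members it exceeded PBS by 0.68, 0.955, 0.658 and 1.19 in that order, in place of 1.04, 1.46, 1.61 and 1.88 by the median. An exact 2-sided permutation test of the median level gave p = 0.1 for each of the 4 groups against PBS (adjusted p = 0.2 over 20 tests), the smallest p that 3 against 3 libraries allow. The same p was reached by erythroid levels below PBS with bortezomib (-0.56), the combination (-0.63) and the delayed combination (-0.56), and in the last also by granulocyte (-0.68), macrophage (0.75) and endothelial levels (1.32). By the mean over members the erythroid level with bortezomib lay above PBS (2.99 against 2.94 log2 CPM). The combination (2.48) and the delayed combination (2.55) stayed below it. Of the markers, 3 erythroid, 3 macrophage and 3 stromal genes exceeded 8 CPM in every library, such as the transferrin receptor TFRC, which tumour cells express as well. Elesclomol 1 had the highest host marker level, 3.55 log2 CPM against 1.94 to 2.75 in the other libraries.

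The 10 genes fixed beforehand passed in none of the comparisons in which edgeR tested them. In the order bortezomib, elesclomol, combination and delayed combination against PBS, PSMB5 (ENSG00000100804), the proteasome subunit that bortezomib binds, was at 0.25 ± 0.19, 0.05 ± 0.19, 0.32 ± 0.18 and 0.27 ± 0.18. FDX1 (ENSG00000137714), the ferredoxin that reduces elesclomol-bound copper, was at 0.06 ± 0.12, -0.05 ± 0.12, 0.00 ± 0.12 and 0.05 ± 0.12. The stress factor DDIT3 was at 0.09 ± 0.21, -0.17 ± 0.21, 0.25 ± 0.21 and 0.10 ± 0.20 and the heme oxygenase HMOX1 at 0.59 ± 0.55, 0.00 ± 0.56, -0.38 ± 0.59 and 0.31 ± 0.53. The cell cycle inhibitor CDKN1A was at 0.11 ± 0.28, -0.32 ± 0.28, 0.31 ± 0.27 and 0.23 ± 0.27. MKI67 was at -0.20 ± 0.19, -0.04 ± 0.19, -0.43 ± 0.19 and -0.42 ± 0.19 and SDC1, the plasma cell marker CD138, at 0.09 ± 0.14, 0.21 ± 0.14, -0.05 ± 0.14 and 0.06 ± 0.14. HSPA1A was at -1.55 ± 0.75, -2.50 ± 0.83, -1.08 ± 0.69 and -2.19 ± 0.73 from a mean of 1.82 CPM with PBS, and is uncertain for the reason given for HSPA1B. The metallothioneins MT1X and MT2A, which bind copper and zinc, had 3 to 14 and 0 to 3 counts per library and were not tested.

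Of the 35 lists, 8 passed in none of the 9 comparisons. Copper handling, the list closest to elesclomol's action, had medians of 0.13 ± 0.22, -0.07 ± 0.12, -0.06 ± 0.24 and 0.09 ± 0.17 against PBS in the same order over 11 genes (smallest camera adjusted p in any comparison 0.206). Protein lipoylation had 0.04 ± 0.25, -0.08 ± 0.17, -0.02 ± 0.18 and 0.04 ± 0.26 (smallest 0.119). Iron-sulfur cluster assembly had 0.10 ± 0.19, 0.00 ± 0.11, 0.03 ± 0.14 and 0.04 ± 0.14 (smallest 0.311). The smallest adjusted p was 0.0863 for the immunoproteasome, 0.118 for B cell genes, 0.161 for NF-kB targets, 0.354 for plasma cell genes and 0.512 for p53 targets. A p that misses the threshold does not show that a list did not change.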

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

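The GC correction, the run without the 3 GC-rich libraries, the host marker covariate as an explanation, and the tumour share were tests chosen after the result was seen, whereas the depth and split tests were set beforehand.

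Some results stood out because elesclomol's change differed with and without bortezomib by a test of that difference. HDAC9 differed by 1.72 in log2 change, but not past the threshold after the GC correction (adjusted p = 0.231). None of the 10 lists that differed held with an estimated correlation (smallest adjusted p = 0.462). The median differences were 0.40 for immediate early, 0.28 for hypoxia and 0.21 for G2 and M genes. They were -1.33 for granulocyte, -1.04 for stromal, -0.41 for interferon, -0.29 for S phase, -0.25 for MYC, -0.18 for 19S and -0.0757 for BH3-only genes. For the gene count of 1, 4 of 100 splits of the 12 libraries gave as many, the real one included, a share under 0.05. Another split gave 892 genes, which points to a structure of the samples. The splits also break up the same-numbered bortezomib and combination libraries, which deviated together, so this share does not exclude chance. For the 10 lists, 48 of 100 splits gave as many, with up to 21, so chance was not excluded.

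For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. Elesclomol against PBS called 9 genes, with 1 of 10 splits as large and 0 as the highest other. In the other 7 comparisons the real count was 0, so that 10 of 10 splits were as large, and the highest other was 1 for the delayed combination against PBS, 964 for the combination against bortezomib and 0 for the rest. The split with 964 genes set bortezomib 1, bortezomib 3 and combination 1 against the others, which points to a structure of the samples. It parts 1 of the 3 same-numbered pairs of these groups, as does the split with 20 lists. Among the 4 splits that part all 3, as the real one does, the highest other was 0 genes by edgeR and 9 lists. List counts and the highest other were 18 and 19 for bortezomib (2 of 10 splits as large), 9 and 10 for elesclomol (4 of 10), 10 and 15 for the combination (7 of 10) and 18 and 14 for the delayed combination (1 of 10) against PBS. They were 8 and 20 for the combination against bortezomib (7 of 10), 9 and 19 against elesclomol (7 of 10), 6 and 18 for the delayed combination against bortezomib (8 of 10) and 8 and 19 against the combination (10 of 10). The correlation of elesclomol's changes with and without bortezomib, -0.254, was reached in size by 33 of 100 splits (farthest other -0.575), and that of bortezomib's, 0.0698, by 81 of 100 (-0.497), so chance was not excluded for either.

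Ribosomal protein genes were higher than PBS with bortezomib, the combination and the delayed combination, and the respiratory chain lists with bortezomib. The ribosomal list stayed called in 3 of 3 after the GC correction (medians 0.19 to 0.14, 0.22 to 0.15 and 0.22 to 0.18). It did so too without the 3 GC-rich libraries (0.12, 0.12 and 0.25). No call held with an estimated correlation (adjusted p = 0.586, 0.776 and 0.576). The corrected first component held 23.5% of variance, so a GC trend is not excluded. Of the 2 respiratory chain lists 1 stayed after the correction, with complex I going from 0.16 to 0.05 (adjusted p = 0.212) and complexes III to V from 0.18 to 0.14 (adjusted p = 0.00112), neither called with an estimated correlation (adjusted p = 0.654 and 0.624), so that a trend cannot be told apart from a response for this pair. Without the 3 GC-rich libraries 0 of 2 stayed (0.03 with adjusted p = 0.334 and 0.06 with adjusted p = 0.0642), consistent with those libraries carrying much of it. The treatments themselves remain an untested explanation for both.

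Immediate early genes were lower than PBS in the 4 treated groups. A GC trend is argued against: the list stayed past the threshold in 4 of 4 comparisons after the GC correction. It also stayed in 4 of 4 thinned to 4500326 counts (medians -0.42, -1.29, -1.09 and -1.43), but thinning keeps proportions and cannot test depth. With an estimated correlation the call held for the delayed combination alone (adjusted p = 0.569, 0.0557, 0.167 and 0.0359). The list stayed in 4 of 4 with the host marker level as a covariate. That level averages lists that moved in opposite directions, so it does not test host cell RNA. This list was put among the gene lists as a sign of handling, since these genes respond within minutes when tissue is collected, and the time and order of collection are not in the labels. A handling difference between PBS and treated mice stays open beside depth, host cell RNA and the treatments, all untested.

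Stromal markers were higher than PBS with elesclomol and the delayed combination. A GC trend is argued against, as the list stayed past the threshold in 2 of 2 comparisons after the correction. It also stayed in 2 of 2 thinned, which leaves depth untested. Neither call held with an estimated correlation (adjusted p = 0.234 and 0.30). The elesclomol median went from 1.53 to 0.54 with the host covariate. A lower share of tumour RNA as the whole cause should raise all marrow markers alike, but with the delayed combination the macrophage (0.75 log2) and endothelial levels (1.32) lay above PBS and the granulocyte (-0.68 ± 0.24) and erythroid levels (-0.56 ± 0.19) below it, and the stromal level moved 2.55 ± 0.41 more than the granulocyte level. With elesclomol that last difference was 0.67 ± 0.95, and a lower tumour share cannot be told apart from other causes because it lies within its spread, with granulocyte levels of 0.95 to 3.85 log2 CPM in the 3 libraries. More stromal cells in the flushed marrow, which may follow from treatment, remain open and untested.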

How the results depend on the processing

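The GC correction, the run without the 3 GC-rich libraries and the paired fit were tests chosen after the result was seen. Unless stated the cause was not tested. All 10 called gene results kept their direction. NXPE3 and DUSP2 passed in 15 of 16 settings, PHLDA1 in 13, DAPK1, F2R and FBXO32 in 11, HDAC9 in 10, FRMD6 in 9, BASP1 in 7, and HDAC9's interaction in 13 of 23. Of 1227 list results under other settings, 882 passed as before, 336 missed the threshold and 9 reversed. Of 8571 results of named genes that had not passed, 366 passed elsewhere. The simulations found 74% to 84% of 2-fold changes, which need not hold in real libraries.

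In the order bortezomib, elesclomol, combination and delayed combination against PBS, combination against bortezomib and elesclomol, delayed combination against bortezomib and the combination, and interaction, edgeR called 0, 9, 0, 0, 0, 0, 0, 0 and 1 genes. With no filter the counts were 76, 129, 211, 193, 14, 291, 25, 1 and 127. By limma voom they were 741, 54, 1394, 168, 35, 205, 7, 0 and 310, and by DESeq2 2, 47, 47, 47, 1, 50, 8, 0 and 32. With only the groups compared, fewer libraries being fitted, elesclomol had 142, the combination 6, the delayed combination 19, the delayed combination against bortezomib 2 and the interaction 5. At 2-fold or more elesclomol had 5. With the host marker level as a covariate elesclomol had 4 (3 of the 9), the combination against elesclomol 6 and the interaction 0, with 6 lists. After the GC correction the delayed combination had 4 genes, the combination against elesclomol 17 and the interaction 2, neither of them HDAC9 (adjusted p = 0.231). Without the 3 GC-rich libraries the counts were 9, 9 and 3 for bortezomib, the combination and the delayed combination against PBS, 4 and 9 for the combination against bortezomib and elesclomol, 2 for the delayed combination against bortezomib and 46 for the interaction. The lists then numbered 11 and 17 for the delayed combination against bortezomib and the combination.

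With a replicate block the combination had 2 genes, the delayed combination 3, the combination against elesclomol 1, the interaction 2 and elesclomol 9, of which 8 were among the 9. Over the 5 groups the numbers did not pair the libraries, as 6 of 30 same-numbered pairs correlated above 0.1 (-0.44 to 0.66) and 6 of 15 libraries correlated best with their own number. All 3 pairs of bortezomib with the combination were above 0.1, as was bortezomib 2 with combination 3. With these 6 libraries alone and their pairs as a replicate block the combination against bortezomib had 5 genes, and 14 with the GC correction added. No list call was lost in either fit.

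Lists called numbered 18, 9, 10, 18, 8, 9, 6, 8 and 10. With an estimated correlation 1 remained for the delayed combination against PBS and 1 against bortezomib, and 0 elsewhere. By fry 1 remained for elesclomol, the combination and the delayed combination against PBS, and 0 elsewhere. Some directions reversed. Granulocyte markers did so with the host covariate, which includes these markers, for elesclomol (adjusted p = 0.423) and the interaction (0.539). Histones did so without bortezomib 1 in the combination against bortezomib (0.293), where leaving out 1 library gave 9.17e-10 to 0.435. They did so too in the delayed combination against bortezomib (0.430, with 1.60e-13 to 0.430 over libraries left out) and without the 3 GC-rich libraries (0.626). In the delayed combination against the combination the immediate early list reversed without combination 1 (0.679, with 8.71e-08 to 0.679 over libraries left out) or the 3 GC-rich libraries (0.656). Without combination 2 complexes III to V reversed (0.916, with 1.69e-08 to 0.916), as did the mitochondrial ribosome (0.966, with 1.12e-05 to 0.966).

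Leaving out 1 library gave 0 to 3 genes (without bortezomib 1) for bortezomib, 1 (without PBS 3) to 6 (without elesclomol 2) for elesclomol, 0 to 6 (without combination 2) for the combination and 0 to 49 (without delayed combination 1) for the delayed combination against PBS. It gave 0 to 0 and 0 to 1 (without elesclomol 3) for the combination against bortezomib and elesclomol, 0 to 6 (without delayed combination 1) and 0 to 0 for the delayed combination against bortezomib and the combination, and 0 to 27 (without bortezomib 1) for the interaction. The list counts ran from 14 to 19, 7 to 11, 8 to 15, 13 to 20, 4 to 18, 5 to 11, 5 to 11, 5 to 17 and 7 to 19. The correlation of elesclomol's changes ran from -0.334 to -0.0966 and was -0.366 over genes of at least 3 log2 CPM. That of bortezomib's ran from -0.131 to 0.255, with -0.0234 without bortezomib 1 and -0.0510 without elesclomol 2, and was -0.0968 without the 3 GC-rich libraries. By the mean over members the stromal level exceeded PBS by 0.68, 0.955, 0.658 and 1.19 for the 4 treatments in the order above.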

Other observations

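The 12 treated against 3 PBS comparison of list levels was among the tests chosen after the result was seen, whereas the test of the ERK pathway was set before its result.

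Taking the 12 treated libraries together against the 3 PBS libraries, 12 of 35 lists had at least 9 of the 12 treated libraries on the same side of all PBS libraries, though none passed. The 4 with the smallest p follow. Immediate early genes were at 3.82 ± 0.94 log2 CPM (SD, n = 12) against 5.58 ± 0.05 (n = 3), below all PBS libraries in 12 of 12, and stromal markers at 3.48 ± 0.53 against 1.98 ± 0.58, above in 12 of 12. BH3-only genes stood at 4.08 ± 0.33 against 3.47 ± 0.02, above in 11 of 12 (combination 2, at 3.49, was not), and genes of the G2 and M phases at 6.04 ± 0.18 against 6.37 ± 0.07, below in 11 of 12. An exact permutation test over 455 splits gave p = 0.0044 for the first 2 lists, the smallest p possible, and 0.00879 for the other 2 lists, all with an adjusted p of 0.0769 over 35 lists. By camera each treatment alone against PBS called the immediate early list, but BH3-only genes were called with bortezomib alone, stromal genes not with the combination and G2 and M genes not with the delayed combination. With an estimated correlation the immediate early call of the delayed combination held (adjusted p = 0.0359), and the others of these calls did not (adjusted p = 0.0557 to 0.776).

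PBS libraries were closer to each other than treated ones: chi-square per degree of freedom between pairs was 2.41 to 3.56 with PBS and 6.30 to 31.3 with treatment. The mitochondrial ribosomal RNA MT-RNR1 stood at 38398 CPM in bortezomib 3 and 40204 CPM in elesclomol 1, against 8308 to 12140 CPM in the other 13 libraries.

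The fall of DUSP2 and PHLDA1 with elesclomol led to the hypothesis that output of the ERK pathway may be lower there, tested on 7 tested output genes other than PHLDA1 from a list fixed before the test. Their median log2 change was -0.24, with 4 of 7 below 0, and DUSP6, a negative feedback phosphatase of ERK, at -0.60 ± 0.22 (adjusted p of the list = 0.327, and 0.517 with an estimated correlation). The test was to count against the hypothesis at an adjusted p of 0.05 or more, but a p that misses the threshold does not exclude a smaller decrease, and with members on both sides of 0 it stays open. The same list lay above PBS with bortezomib (median 0.41, adjusted p = 0.0160), the combination (0.33, 0.0160) and the delayed combination (0.40, 0.0233), each with an adjusted p = 0.180 with an estimated correlation.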
